A study of Homo sapiens with 21 samples.

How the data were processed

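RNA from human aortic endothelial cells (HAEC, primary cells lining the aorta) was sequenced after exposure to 1 of 2 shear regimes or without flow. Per the labels, pulsatile shear had a mean of 12 with a swing of 4 dyn/cm2, oscillatory shear had a mean of 0.5 with a swing of 4 dyn/cm2, and cells were collected after 1, 4 and 24 h of either. Static cells were collected at 0 h only. Each of the 7 groups held 3 replicates, which gave 21 libraries. Ribosomal RNA had been depleted, the kit was a stranded one, and reads were single-ended with a length of 75 bases. Whether the replicates came from separate donors is not stated in the labels, and no batch is given.

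The deposited table holds 1 estimated count per gene and library (expected counts), which the authors left unscaled. These estimates were made on the hg19 build with refGene gene models, and the program that aligned or counted the reads is not given in the sources used here. Of the estimates above 0, 17% were not whole numbers (tolerance 1e-06), so some reads had been divided between genes. Whether counting was restricted to 1 strand was not stated. The table lists 22351 genes. Y-linked genes, XIST and TSIX (126 genes) were left out of every step to protect the donors, which left 22225. All columns of per-sample values were used.

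Library totals ran from 14.2 to 20.2 M estimated counts (M, mega). All intervals and floors cover counting error only, since the reads carried no molecular identifiers. Where a group held fewer than 30 counts of a named gene, a ratio of counts with a 95% interval is given in place of a fitted fold. Changes of a difference between times are fitted values throughout, also where counts were few.

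Estimates were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 on the 7 groups, which left 13469 genes for testing. Libraries were scaled with TMM factors. A quasi-likelihood model with robust estimation and 1 mean per group was fitted to all 21 libraries together, which left 14 residual degrees of freedom. Each comparison was a contrast of group means tested with the two-sided quasi-likelihood F test. P-values were adjusted by Benjamini and Hochberg over all genes of a comparison, and a gene was called changed at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are counts per M counts (CPM) scaled by the TMM factors, given as the mean with the standard deviation (SD) of 3 libraries. The values of 24 tested genes were identical in all libraries to those of another gene of the table.

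The comparisons were pulsatile against oscillatory flow at each time, each flow against static cells at each time, 4 against 1 h and 24 against 4 h within each flow, and the change of the pulsatile to oscillatory difference from 1 or 4 h to 24 h (an interaction). Since static cells were taken at 0 h only, flow and time in culture cannot be told apart in comparisons with static cells. The overlap of the responses of both flows was set against 20 simulations in which all libraries were drawn around the static means, because both comparisons share the same 3 static libraries.

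Before the data were examined, 36 gene lists were written from textbook knowledge, covering flow-responsive, inflammatory, stress, metabolic, cell cycle and signalling genes, markers of other cell types and signs of RNA quality. Of their 636 symbols, 619 were found in the table, and 34 lists had at least 3 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and adjusted over the 34 lists of a comparison. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way without setting them against other genes. Members were also counted after adjustment over the list alone.

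Genes named in the text were chosen by a rule written before the data were examined. It takes, for each pulsatile to oscillatory comparison, the 6 genes with the highest and the 6 with the lowest log2 fold change, and for each comparison with static cells the 3 highest and the 3 lowest. These had to be called, to have a mean of at least 5 CPM in the higher group, to have no overlap between the replicates of the groups compared, and to have a gene symbol other than a clone or locus name. A fixed panel of endothelial genes is given for every pulsatile to oscillatory comparison, and a few genes under the rule are not reported here. From each list whose test passed, up to 4 members with the smallest p were taken. AHR, AHRR, TIPARP and ALDH3A1 were added after their values were seen.

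Alternatives fixed in advance were RLE size factors, library totals alone, no filter except on genes at 0 throughout, a stricter filter (at least 1 CPM in at least 3 libraries), the replicate number as a block, the fit without robust estimation, a fit of the contrasted groups alone, the DESeq2 1.42.0 Wald test, limma-voom, an adjusted p of 0.01, glmTreat against a 1.5-fold change, and leaving out each library in turn. Added after seeing the data were the removal of each library's trend on exon length and GC content, a fit without RPPH1 and RMRP, and the main axis of variation within groups as a further term. With the trend removed, lists were tested on log2 CPM, whereas the main list test used the counts. List calls that differ between the 2 cannot be credited to the trend alone. Exon lengths came from the deposited table. GC content came from GENCODE transcripts matched by gene symbol, and was known for 12932 of the tested genes (96%). A change of sign was counted as a reversal only where the gene was called in at least 1 of the settings compared.

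The pipeline was tested on simulated data in which 200 genes differed between groups built on the 24 h libraries. It recovered 36% of the genes changed by 1.2-fold (18 of 50), 77.6% of those changed by 1.5-fold, 85.7% at 2-fold and 95.9% at 4-fold. Of 156 calls, 11 were false (7.05%), and 0 had the wrong direction. A simulated raised list passed (adjusted p = 3.05e-39), and 0 of 33 unchanged lists passed. Simulated genes were drawn independently of each other, so these list results do not test the preset correlation between genes. Pairs of replicates differed by more than counting error, with a chi-square per degree of freedom of 1.85 to 6.41.

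Principal components were computed on log2 CPM. Counts of called genes were also made after every other split of the libraries into groups of the same sizes, of which 3 against 3 allows 10, and for the interactions over 100 splits, of which 99 were drawn with a fixed seed beside the real one. The p-values measure the spread between these samples, and they carry over to other donors only if the replicates were separate donors.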

Results

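The series followed human aortic endothelial cells through 24 h of 2 kinds of flow. Pulsatile shear, with a high forward mean, is the kind found in straight arteries that stay free of plaque, and oscillatory shear, with a mean near 0, is the kind found where plaques form. Gene expression was measured by RNA sequencing in 7 groups of 3 libraries, namely static cells at 0 h and cells under pulsatile or oscillatory shear for 1, 4 and 24 h. Library totals ran from 14.2 to 20.2 M estimated counts (M, mega). Group means were 18.11 ± 2.04 M (SD, n = 3) in static cells, 18.58, 16.97 and 15.79 M after 1, 4 and 24 h of oscillatory flow, and 17.6, 17.68 and 17.19 M after the same times of pulsatile flow. The first principal component held 56.6% of the variance and the second 12.2%. Positions of genes are on hg19.

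**Figure D1:**
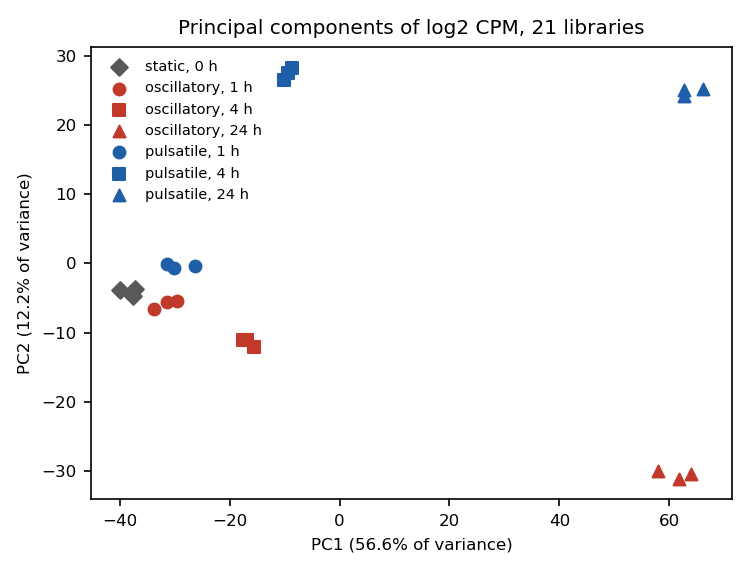
Principal components of log2 CPM, with 1 point per library, coloured by flow and shaped by time; the axes give component scores. The first component (56.6% of variance) and the second (12.2%) place the 3 libraries of each group near each other.

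Pulsatile and oscillatory flow were compared at 1 h to ask how cells tell the 2 kinds of shear apart early. KLF2, a transcription factor induced by laminar shear that keeps endothelium quiescent, led the difference with 57.32 ± 3.58 CPM in pulsatile and 4.47 ± 0.632 CPM in oscillatory flow (SD, n = 3), a 12.7-fold higher level. The related factor KLF4 stood 8.71-fold higher (26.42 ± 4.28 against 3.005 ± 0.854 CPM). EDN1, which encodes the vasoconstrictor endothelin-1, was lower in pulsatile flow (438.8 ± 25.6 against 816 ± 28.8 CPM), while HEY1, a Notch target, was higher (72.34 ± 4.77 against 31.74 ± 4.1 CPM). Of 13469 genes tested, 659 were called, 438 higher and 221 lower in pulsatile flow, and 42 and 21 of them by at least 2-fold.

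The log2 fold change of KLF2 (chromosome 19, 16435651 to 16438339) was 3.67 (SE 0.0889, adjusted p = 9.42e-30), and that of KLF4 (chromosome 9, 110247133 to 110252047) was 3.12 (SE 0.192, adjusted p = 4.45e-09). DDIT4, an inhibitor of mTORC1 signalling (1.79), S1PR2, a sphingosine-1-phosphate receptor (1.65), ANGPTL4, an inhibitor of lipoprotein lipase (1.61), and ARC (1.49) completed the 6 highest. C10orf10 was the lowest (log2 fold change -2.24, SE 0.146, adjusted p = 4.81e-08; chromosome 10, 45471709 to 45474330). It was followed by the homeobox gene HLX (-2.21), the cAMP phosphodiesterase PDE4B (-2.09), SPRY1, an inhibitor of growth factor signalling (-1.95), the kinase PDK4, which restrains pyruvate oxidation (-1.77), and F3, the initiator of coagulation (-1.61). Estimates of S1PR2 were fractional in 17 libraries. The model of C10orf10 overlaps RASSF4, its estimates were fractional in 0 libraries, and whether it holds reads of RASSF4 was not tested.

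Among the panel genes at 1 h, the chemokine gene CCL2 (1.23, adjusted p = 2.35e-05) and the adhesion molecule ICAM1 (0.50, adjusted p = 5.59e-05) were higher in pulsatile flow. The YAP target genes CTGF (-0.48, adjusted p = 3.42e-10) and CYR61 (-0.70, adjusted p = 2.24e-06) were lower. The call of HMOX1, the heme-degrading enzyme (-0.53, adjusted p = 0.0127), was lost without replicate 1 of pulsatile flow and in a fit of the contrasted groups alone. ID1 (0.52, adjusted p = 0.0201) passed, but lost its call in 3 of the 6 fits without 1 library of these groups. The adhesion molecules VCAM1 (-0.29, adjusted p = 0.506) and SELE (-0.76, adjusted p = 0.185) did not pass, nor did NOS3, the endothelial nitric oxide synthase (0.09, adjusted p = 0.689), or THBD, the anticoagulant thrombomodulin (-0.26, adjusted p = 0.231), although THBD passed with the main axis of variation within groups as a term. PTGS2, EGR1, FOS, NQO1, ANKRD1, MKI67 and PECAM1 lay between -0.42 and 0.06 and did not pass.

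Gene groups at 1 h were led by Notch and arterial genes, of which 10 of 17 were higher and 1 lower in pulsatile flow (12 and 2 when adjusted over the list alone; list median 0.487, adjusted p = 2.68e-20). LFNG (1.07), GJA5, a gap junction protein of arteries (1.11), and NRARP (0.75) rose beside HEY1 (1.19). Of 19 immediate early genes, the first to answer a stimulus, 9 were higher and 1 lower (11 and 2 adjusted over the list alone; median 0.392, adjusted p = 3.92e-15), among them JUNB (0.92) and DUSP1 (0.83). Only 3 of 16 KLF-regulated vasoprotective genes were higher and 0 lower (5 and 1 adjusted over the list alone; median 0.136, adjusted p = 8.31e-16), and these were KLF2, KLF4 and CYP1B1 (1.10). CYP1B1 and its list neighbour CYP1A1 are also known as targets of the aryl hydrocarbon receptor. Of 18 ATF4 amino acid response genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone; median 0.0262, adjusted p = 8.65e-09), with DDIT4 and TRIB3 (0.60) among the 5. These 4 lists also passed with an estimated correlation (adjusted p = 0.00735, 0.00229, 0.00229 and 0.0372).

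Among BMP-SMAD target genes, 5 of 13 were higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 8.52e-05, but adjusted p = 0.239 with an estimated correlation). SMAD7, a feedback inhibitor of the pathway, rose by 0.92, and SMAD6 (0.72), HEY2 (0.36) and ID3 (0.37) passed but lost their calls under at least 1 alternative. The 15 clock genes passed (median 0.13, adjusted p = 0.00126, adjusted p = 0.0136 with an estimated correlation), with BHLHE40 higher (1.01) and NR1D2 lower (-0.28, a call lost without replicate 3 of pulsatile flow), and 3 higher and 1 lower adjusted over the list alone. Small shifts gave a call at the preset correlation to cytosolic ribosomal protein genes (median -0.0887, 0 higher and 1 lower of 20, 0 and 6 adjusted over the list alone, adjusted p = 7.59e-05), replication-dependent histone genes (median -0.11, 0 and 1 of 14, 0 and 4 over the list alone, adjusted p = 0.0018), nuclear respiratory chain genes (0 of 21 called), NRF2 antioxidant genes (0 and 3 of 20, 0 and 4 adjusted over the list alone) and NF-kB inflammatory genes (5 and 1 of 22, 7 and 2 adjusted over the list alone). With an estimated correlation these 5 had adjusted p = 0.525, 0.525, 0.58, 0.525 and 0.525.

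Across 9655 genes, log2 fold changes at 1 h rose with exon length (Spearman rho 0.32, over genes, which are not independent replicates), against -0.116 at 4 h and -0.119 at 24 h. With each library's trend on exon length and GC content removed, an alternative added after seeing the data, 6 list calls at 1 h were lost. Lists were then tested on log2 CPM instead of counts, and log2 CPM with the trend left in were not tested. A lost call can therefore come from the change of test as well as from the trend. The medians of log2 CPM differences went to near 0 for ribosomal protein (-0.0889 to -0.0206, adjusted p = 0.186), histone (-0.112 to 0.00575, adjusted p = 0.565) and respiratory chain genes (-0.0453 to 0.0045, adjusted p = 0.69). They stayed about as large for NF-kB (0.106 to 0.119, adjusted p = 0.065), clock (0.107 afterwards, adjusted p = 0.065) and NRF2 genes (-0.0307 to -0.0241, adjusted p = 0.098). The removal left the calls of the Notch (0.485 to 0.49, adjusted p = 3.21e-13), immediate early (0.393 to 0.391, adjusted p = 1.94e-09) and ATF4 lists (0.0274 to 0.0293, adjusted p = 0.00117). The KLF-regulated list also passed, but its median fell from 0.137 to 0.0759 (adjusted p = 0.00863).

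**Figure D2:**
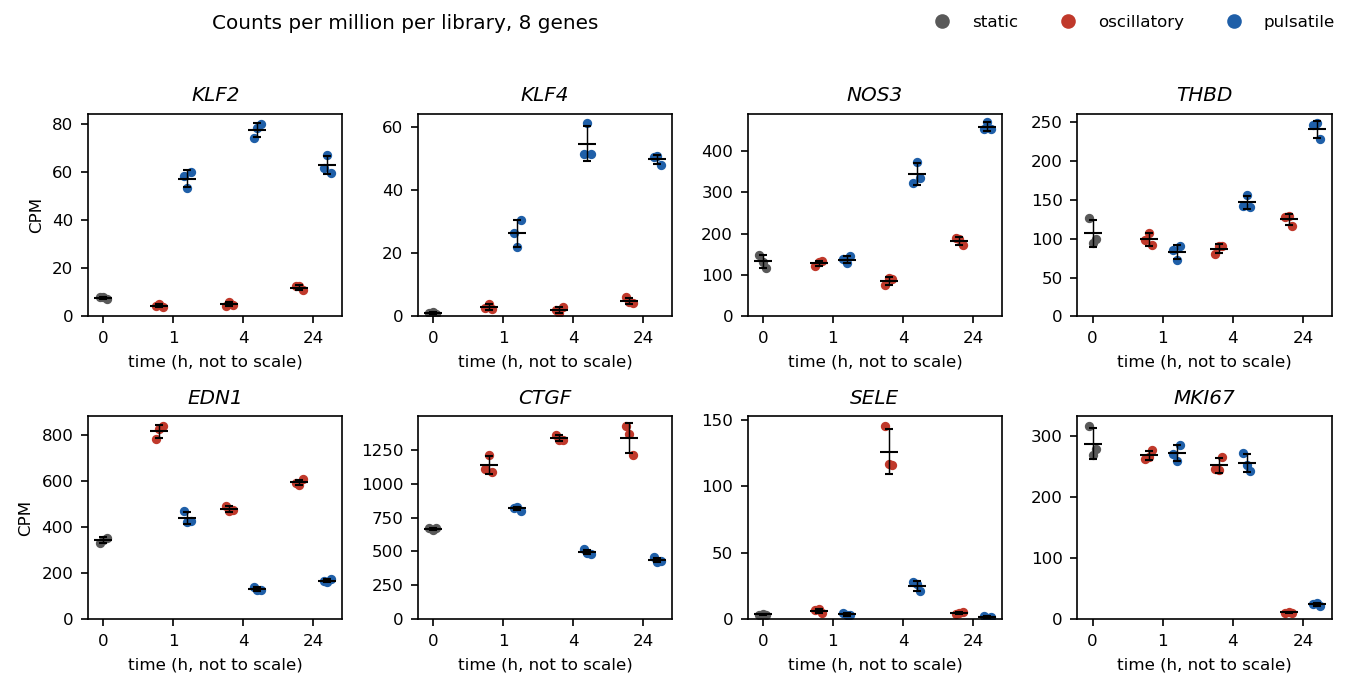
Levels of 8 panel genes in CPM (vertical axes) by hours of flow (horizontal axes, not to scale), with 1 point per library and the mean and SD of 3 libraries per group; static cells stand at 0 h. KLF2 reached 57.32 CPM after 1 h of pulsatile flow and 4.47 CPM after 1 h of oscillatory flow, and SELE reached 126.2 CPM after 4 h of oscillatory flow.

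At 4 h the comparison asked how far the 2 programs had moved apart. NOS3 was 343.1 ± 26.9 CPM in pulsatile and 85.93 ± 9.66 CPM in oscillatory flow (SD, n = 3; log2 fold change 2.00, SE 0.0891, adjusted p = 7.67e-12), although its gene model overlaps ATG9B. SELE, the E-selectin that tethers leukocytes, was 25.22 ± 3.86 CPM in pulsatile and 126.2 ± 16.8 CPM in oscillatory flow (-2.32, SE 0.143, adjusted p = 2.42e-09), and VCAM1 and CCL2 were lower in pulsatile flow as well (-1.16 and -1.13). KLF2 and KLF4 stayed higher (3.93 and 4.75). EDN1 was lower at 4 h too, at 130.8 ± 6.82 against 478.6 ± 11.3 CPM (-1.87). In all, 3603 genes were called, 1834 higher and 1769 lower in pulsatile flow, 311 and 145 of them by at least 2-fold.

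NOV, a matricellular protein of the CCN family, had the highest log2 fold change (5.16, SE 0.166, adjusted p = 3.65e-26; chromosome 8, 120428552 to 120436678). APOL4 (a count ratio of 33 with a 95% interval of 19.8 to 59.5), the water channel AQP1 (4.68) and MN1 (4.12) followed beside KLF4 and KLF2. The chemokine receptor CXCR4 was lowest (-2.85, SE 0.123, adjusted p = 1.95e-11; chromosome 2, 136871919 to 136875725), followed by FILIP1 (-2.73), GALNTL2 (-2.67), the Tie2 antagonist ANGPT2 (-2.46, its model overlaps MCPH1), F3 (-2.43) and SELE. In the panel, THBD was now higher (0.75, adjusted p = 4.25e-05), as were ICAM1 (0.39), NQO1 (0.27), ANKRD1 (0.40), ID1 (0.50) and PECAM1 (0.16). PTGS2 (-0.45), EGR1 (-2.24), HMOX1 (-0.58), CTGF (-1.43) and CYR61 (-0.99) were lower. HEY1 (0.34, adjusted p = 0.0694), FOS (-0.04) and MKI67 (0.02) did not pass, although HEY1 passed under 4 alternatives.

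Of the 16 KLF-regulated genes, 10 were higher and 1 lower at 4 h (12 and 1 adjusted over the list alone; median 1.54, adjusted p = 9.91e-47), with GCH1, which makes the cofactor of nitric oxide synthase (2.43), and the angiopoietin receptor TEK (1.14) among them. Endothelial identity markers followed with 12 of 19 higher and 1 lower (14 and 1 adjusted over the list alone; median 0.303, adjusted p = 3.56e-09), led by the VEGF receptor KDR (1.14), TEK, MMRN2 (0.89) and LYL1 (0.80). On mean log2 CPM, the median difference of the KLF-regulated list was 1.04, and 1.03 with the length and GC trend taken out. The KLF-regulated and endothelial identity lists held with an estimated correlation (adjusted p = 9.96e-06 and 0.0421). So did the epithelial markers, where 2 of 3 tested members, KRT19 (1.33) and KRT18 (0.69), were higher (2 and 0 adjusted over the list alone; adjusted p = 3.87e-05 and 0.0415 with an estimated correlation). Angiogenic tip cell genes moved both ways, 5 higher and 8 lower of 18 (8 and 8 adjusted over the list alone; median -0.0766, adjusted p = 4.7e-05, but adjusted p = 0.11 with an estimated correlation), with PGF, a VEGF family ligand, lower (-1.05).

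NRF2 genes were also split at 4 h, 6 higher and 9 lower of 20 (7 and 10 adjusted over the list alone; adjusted p = 0.0293), with SLC7A11, the cystine transporter (-0.64), and TXNRD1 (-0.66) lower. Immediate early genes were 8 higher and 6 lower of 19 (8 and 7 adjusted over the list alone; adjusted p = 0.0311), with NR4A1 higher (2.28). Both had adjusted p = 0.618 with an estimated correlation. With the length and GC trend taken out neither list passed, while the median log2 CPM difference went from -0.128 to -0.101 for NRF2 (adjusted p = 0.0642) and from 0.016 to -0.00811 for immediate early genes (adjusted p = 0.449). Of 22 NF-kB genes 11 were lower and 3 higher (12 and 4 adjusted over the list alone, median -0.313), but the list did not pass (adjusted p = 0.0553), and it passed as lower with that trend taken out (adjusted p = 0.0205). Further lists passed only with the trend taken out. These were ATF4 genes as lower (adjusted p = 0.0157), and endoplasmic reticulum chaperone and interferon-stimulated genes as higher (adjusted p = 0.0182 and 0.0206).

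At 24 h, the latest time, 5295 genes were called, 2985 higher and 2310 lower in pulsatile flow, 440 and 260 of them by at least 2-fold. TEK stood at 697.3 ± 48.5 CPM in pulsatile and 180.8 ± 7.79 CPM in oscillatory flow (SD, n = 3), while its antagonist ANGPT2 stood at 12.33 ± 2.08 and 139 ± 3.51 CPM. The matrix protease ADAMTS1 reached 1587 ± 38.1 against 99.43 ± 5.02 CPM. NOS3 (457.9 ± 10.4 against 182.6 ± 9.43 CPM) and THBD (241.1 ± 11.1 against 124.8 ± 7.47 CPM) were higher in pulsatile flow, and MKI67, a proliferation marker, was 24.14 ± 2.74 against 10.81 ± 0.989 CPM.

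The largest difference at 24 h was that of PI16 (chromosome 6, 36916039 to 36932613), with 67.03 ± 3.2 CPM in pulsatile flow and 3 counts in all oscillatory libraries, a count ratio of 1060 (95% interval 364 to 5160). All 3 counts came from replicate 3, so the size of this ratio rests on 1 library, without which the count in oscillatory flow is 0. The chemerin receptor CMKLR1 had a ratio of 162 (55.2 to 789), LCN6, which overlaps another gene model, of 87.5 (33.9 to 323), and NOV of 51.6 (33.9 to 82.6). The oscillatory counts were 3 for CMKLR1, of which 2 came from replicate 1, and 4 for LCN6, of which 3 came from replicate 3, so these ratios also rest mostly on 1 library each. STC1 (log2 fold change 5.44, SE 0.117, adjusted p = 2.41e-32) and AQP1 (5.32) followed. ANGPT2 was lowest (-3.50, SE 0.0697, adjusted p = 1.16e-31; chromosome 8, 6357175 to 6420784), before the mast cell protease CPA3 (-3.10), NUPR1 (-3.03, overlapping EIF3C), FILIP1 (-2.78), ESM1, a tip cell proteoglycan (-2.74), and CXCR4 (-2.54). Panel genes higher in pulsatile flow were KLF2 (2.40), KLF4 (3.34), NOS3 (1.33), THBD (0.95), ICAM1 (0.40), NQO1 (0.64), MKI67 (1.16), PECAM1 (0.47) and ID1 (0.37, adjusted p = 0.0363), and the call of ID1 was lost without any 1 of the 6 libraries. SELE (-1.49), EDN1 (-1.83), PTGS2 (-0.52), EGR1 (17 counts, lower by a count ratio of 7.77, 95% interval 4.66 to 13.8), HMOX1 (-0.42), CTGF (-1.61) and CYR61 (-1.45) were lower. VCAM1 (0.55, adjusted p = 0.0726), CCL2 (0.66, adjusted p = 0.121), FOS (-0.78, adjusted p = 0.0788), HEY1 (0.18) and ANKRD1 (0.02) did not pass. VCAM1 passed with the replicate number as a block and without replicate 2 of pulsatile flow, and CCL2 passed under 5 alternatives.

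All but 2 of the 16 KLF-regulated genes were higher at 24 h (14 higher and 0 lower, also adjusted over the list alone; median 1.79, adjusted p = 1.96e-40), among them the arginine-recycling enzyme ASS1 (3.35). Of 18 ATF4 genes, 15 were lower and 1, DDIT4 (1.77), was higher (16 and 1 adjusted over the list alone; median -1.01, adjusted p = 5.33e-14), with ASNS (-1.45), PSAT1 (-1.44) and MTHFD2 (-1.28), which serve amino acid and folate synthesis, among the lower. Endothelial identity markers were 8 higher and 2 lower of 19 (9 and 2 adjusted over the list alone; median 0.199, adjusted p = 1.16e-09), with CD34 (3.03), MMRN2 (1.24) and KDR (0.74). Tip cell genes were 5 higher and 10 lower of 18 (5 and 11 adjusted over the list alone; median -0.4, adjusted p = 1.2e-07), with PGF (-1.94) and PDGFB (-1.30) lower. These 4 lists passed with an estimated correlation (adjusted p = 1.79e-05, 0.0155, 0.0318 and 0.0318).

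Mitotic genes were higher in pulsatile flow in 20 of 20 cases at 24 h (20 and 0 adjusted over the list alone; median 0.855, adjusted p = 1.57e-09, but adjusted p = 0.0752 with an estimated correlation), including TOP2A (1.45) and KIF20A (1.52, overlapping CDC23). Cholesterol synthesis genes under SREBP2 were lower in 20 of 23 cases and higher in 0 (21 and 0 adjusted over the list alone; median -0.483, adjusted p = 1.53e-11, but adjusted p = 0.0962 with an estimated correlation), including DHCR7 (-0.79) and SQLE (-0.63). Interferon-stimulated genes were higher in 9 of 20 (10 and 0 adjusted over the list alone; adjusted p = 0.0157), with OAS2 (2.11) and OAS1 (2.55). Basement membrane and matrix genes were 11 higher and 4 lower of 24 (11 and 4 adjusted over the list alone; adjusted p = 0.00226), with ADAMTS1 (4.00) and elastin, ELN (a count ratio of 15.5, 95% interval 9.63 to 26.5), higher and the collagen cross-linker LOX lower (-0.94). Both had adjusted p = 0.345 with an estimated correlation. Replication-dependent histone genes were higher in 10 of 14 (10 and 0 adjusted over the list alone; adjusted p = 0.00615, but adjusted p = 0.551 with an estimated correlation).

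Actin and SRF target genes were 9 lower and 5 higher of 21 (10 and 5 adjusted over the list alone; adjusted p = 0.00609, but adjusted p = 0.234 with an estimated correlation), with CNN2 (-0.69) and CALD1 (-0.62) lower. YAP/TAZ target genes were 9 lower and 6 higher of 20 (the same adjusted over the list alone; adjusted p = 0.0186, but adjusted p = 0.345 with an estimated correlation), with AMOTL1 (1.02) and NT5E (0.67) higher beside the lower CTGF. Of 5 smooth muscle markers, RGS5 alone was called (1.94; 1 and 0 adjusted over the list alone; list adjusted p = 0.0157, but adjusted p = 0.0752 with an estimated correlation). With the length and GC trend taken out the YAP/TAZ (adjusted p = 0.245) and smooth muscle (adjusted p = 0.271) lists did not pass, although their median log2 CPM differences did not shrink much (-0.0659 to -0.0787 and 0.233 to 0.23). NRF2 genes (median -0.207, adjusted p = 0.0283) and DNA replication genes (median 0.241, adjusted p = 0.00526) passed there, but not in the main test (adjusted p = 0.145 and 0.123).

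**Figure D3:**
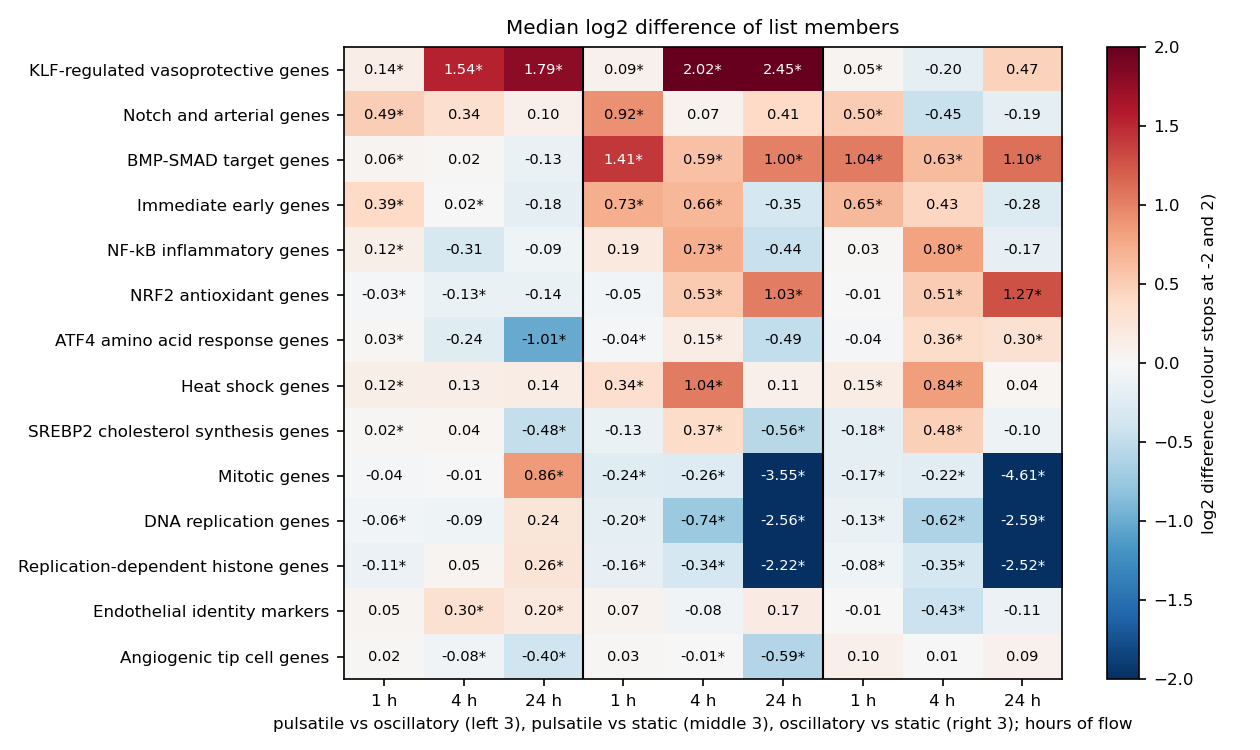
Median log2 fold change (colour and number) of 14 gene lists (vertical axis) in 9 comparisons (horizontal axis), with stars where the list test had an adjusted p under 0.05 at the preset correlation and colours that stop at -2 and 2. Between pulsatile and oscillatory flow, the median of the KLF-regulated list was 0.136 at 1 h, 1.54 at 4 h and 1.79 at 24 h. The list test of its shift from 4 to 24 h did not pass (adjusted p = 0.471).

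Of all tested genes, 146 were higher and 119 lower in pulsatile flow at each of the 3 times. Between 4 and 24 h, 1182 genes were higher at both times (406 if calls were independent), 1063 lower at both (303) and 140 opposite (707). Between 1 and 24 h, 164 were higher at both (97.1 if independent), 134 lower at both (37.9) and 93 opposite (124). Leaving out 1 library moved the 1 h count to between 423 (without replicate 1 of oscillatory flow) and 567, and it was 430 without replicate 3 of pulsatile flow. Against a change of 1.5-fold, glmTreat called 59, 490 and 836 genes at 1, 4 and 24 h.

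Each flow was compared with static cells to ask how cells under either differ from cells without flow. After 1 h, CYP1B1, a cytochrome P450, had 2 counts in all static libraries together, and its count ratio was 980 (95% interval 271 to 8100) under pulsatile and 456 (126 to 3770) under oscillatory flow (chromosome 2, 38294746 to 38303323). SMAD7 rose from 3.298 ± 0.893 CPM to 79.6 ± 4.97 and 42.18 ± 2.34 CPM (SD, n = 3; log2 fold changes 4.62 and 3.70), and PTGS2, the prostaglandin-forming COX-2, rose by 3.55 and 3.58. KLF4 rose by 4.68 (SE 0.24, adjusted p = 1.26e-10) under pulsatile flow, and CYP1A1 by 3.81 (SE 0.222, adjusted p = 8.71e-09) under oscillatory flow. KLF2 rose by 2.90 under pulsatile flow and fell by 0.77 under oscillatory flow. C10orf10 (-3.77), SPRY1 (-3.09) and HLX (-2.43) fell most under pulsatile flow, and C10orf10 (-1.54), RGS2 (-1.44) and TXNIP (-1.31) under oscillatory flow.

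BMP-SMAD targets rose after 1 h in 8 of 13 cases under pulsatile flow (median 1.41, adjusted p = 2.43e-54) and in 9 under oscillatory flow (median 1.04, adjusted p = 8.57e-71), with 0 lower and the same counts adjusted over the list alone. ID2 rose by 3.27 and 3.09. Of 17 Notch and arterial genes, 15 rose and 1 fell under pulsatile flow (16 and 1 adjusted over the list alone; median 0.919, adjusted p = 8.44e-43). Of these genes 10 rose and 0 fell under oscillatory flow (11 and 1; median 0.502, adjusted p = 1.55e-26), with HEY1 at 4.01 and 2.82. Of 19 immediate early genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone; adjusted p = 2.43e-17) and 10 rose and 3 fell (10 and 3; adjusted p = 1.83e-06), with JUNB at 3.00 and 2.08. All of these held with an estimated correlation (largest adjusted p = 0.0412). Mitotic genes were already lower in 18 of 20 cases under pulsatile flow (median -0.237, adjusted p = 1.43e-08) and in 9 under oscillatory flow (18 in both when adjusted over the list alone; median -0.174, adjusted p = 8.09e-09), with adjusted p = 0.0662 and 0.0619 with an estimated correlation. Log2 fold changes of these comparisons rose with exon length (rho 0.363 and 0.202). Beside the mitotic genes, ribosomal protein genes were lower under pulsatile flow in 8 of 20 cases (16 adjusted over the list alone; median -0.116, adjusted p = 0.00135, but adjusted p = 0.609 with an estimated correlation). Respiratory chain genes were lower there in 5 of 21 (also adjusted over the list alone; median -0.0892, adjusted p = 0.00827, but adjusted p = 0.521 with an estimated correlation). With the length and GC trend taken out, the median log2 CPM differences of those 2 lists were 0.00695 and -0.00337 and neither passed (adjusted p = 0.924 and 0.744). Replication-dependent histone genes were lower under both flows (8 and 2 of 14, 9 and 3 adjusted over the list alone; medians -0.162 and -0.0829, adjusted p = 5.73e-05 and 0.0147, but adjusted p = 0.374 and 0.612 with an estimated correlation). With the trend taken out their medians were -0.0443 and -0.0527 (adjusted p = 0.0496 and 0.0299). Those of the mitotic genes went from -0.237 to -0.184 and from -0.173 to -0.139 and passed (adjusted p = 1.55e-07 and 6.86e-07). Under pulsatile flow the ATF4 list passed as higher (adjusted p = 0.0297, but adjusted p = 0.497 with an estimated correlation and adjusted p = 0.662 with the trend taken out) with a mean of 0.111 and a median of -0.0382. That comparison called 2632 genes, 1416 higher and 1216 lower, and oscillatory flow called 1019, 582 higher and 437 lower. Without 1 library these counts ran from 1477 (without replicate 3 of pulsatile flow) to 2895 and from 538 (without replicate 2 of oscillatory flow) to 1032; without replicate 2 of static cells they were 1739 and 620, and the count for oscillatory flow was 657 without replicate 3 of static cells. With RLE size factors the split for pulsatile flow was 1258 higher and 1682 lower.

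After 4 h, CYP1B1 had a count ratio to static cells of 5320 (95% interval 1470 to 43900) under pulsatile and 839 (232 to 6930) under oscillatory flow. CYP1A1 rose by 6.31 under pulsatile flow, and from 4.1 to 258 CPM under oscillatory flow. KLF4 rose by 5.72 under pulsatile flow, and SELE by 5.19 (SE 0.193, adjusted p = 2.34e-12) under oscillatory flow, from 3.464 ± 0.138 to 126.2 ± 16.8 CPM (SD, n = 3). EDN1 fell by 1.39 under pulsatile flow and rose by 0.48 under oscillatory flow. The receptor KIT (-3.88), SCHIP1 (-3.58) and CXCR4 (-3.56) fell most under pulsatile flow, and the death ligand TNFSF10 (-3.05), SCHIP1 (-2.87) and INHBB (-2.63) under oscillatory flow; estimates of SCHIP1 were fractional in 20 libraries. Pulsatile flow called 6607 genes, 3443 higher and 3164 lower, and oscillatory flow 6248, 3106 higher and 3142 lower. Scaled by library totals alone, these splits were 2771 and 4157, and 2470 and 4151.

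NRF2 genes rose after 4 h in 19 of 20 cases under pulsatile flow (median 0.525, adjusted p = 2.35e-25) and in 17 with 1 lower under oscillatory flow (median 0.51, adjusted p = 1.29e-40). DNA replication genes were lower in 19 of 20 cases under both flows (medians -0.744 and -0.618, adjusted p = 1.38e-16 and 1.9e-13). Adjusted over the list alone, these 4 counts were the same, and all 4 held with an estimated correlation (largest adjusted p = 0.0202). Histone genes were lower beside them in 13 of 14 cases under either flow (the same adjusted over the list alone; medians -0.344 and -0.351, adjusted p = 8.14e-05 and 1.53e-06, but adjusted p = 0.269 and 0.21 with an estimated correlation). They passed with the length and GC trend taken out (medians -0.259 and -0.235, adjusted p = 0.000153 and 7.46e-05). Heat shock genes rose in 14 of 15 cases under either flow, with 0 and 1 lower, and the chaperone gene HSPA8 rose by 1.19 and 0.97 (list medians 1.04 and 0.843, adjusted p = 5.75e-11 and 4.88e-10, but adjusted p = 0.094 and 0.0947 with an estimated correlation; 14 and 14 adjusted over the list alone). Endoplasmic reticulum chaperone genes rose in 17 and 18 of 18 cases (the same adjusted over the list alone; adjusted p = 1.61e-14 and 1.74e-11, with an estimated correlation adjusted p = 0.0466 and 0.0599). NF-kB genes rose in 16 of 22 cases with 2 lower under oscillatory flow (the same adjusted over the list alone; median 0.803, adjusted p = 1.88e-09, adjusted p = 0.0202 with an estimated correlation), and in 13 with 5 lower under pulsatile flow (adjusted p = 0.000208, but adjusted p = 0.112 with an estimated correlation).

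Endothelial identity markers fell in 17 of 19 cases after 4 h of oscillatory flow (17 lower and 1 higher adjusted over the list alone; median -0.429, adjusted p = 2.27e-10, adjusted p = 0.0202 with an estimated correlation), with CD34 at -1.80 and KDR at -0.78. Of 3 epithelial markers, 2 were lower beside them (3 adjusted over the list alone; median -0.775, adjusted p = 0.00113, but adjusted p = 0.0599 with an estimated correlation). The list passed with the length and GC trend taken out (adjusted p = 0.00585). Under oscillatory flow the epithelial list was also lower at 1 h (median -0.208, adjusted p = 0.0287, but adjusted p = 0.207 with an estimated correlation). It was lower at 24 h as well (median -1.32, adjusted p = 0.000712, but adjusted p = 0.0525 with an estimated correlation). Under pulsatile flow the epithelial list did not pass at 4 h (adjusted p = 0.832) and was lower at 24 h (2 of 3; median -0.983, adjusted p = 0.0147, but adjusted p = 0.141 with an estimated correlation and adjusted p = 0.0909 with the trend taken out, at a median of -0.945). The endothelial identity list had 4 higher and 7 lower after 4 h of pulsatile flow and did not pass (adjusted p = 0.29). The KLF-regulated list rose under pulsatile flow, 12 higher and 1 lower of 16 (13 and 2 adjusted over the list alone; median 2.02, adjusted p = 2.58e-32; median difference of mean log2 CPM 1.23, and 1.14 with the length and GC trend taken out), and did not pass under oscillatory flow with 3 higher and 6 lower (adjusted p = 0.223). The flow comparison at 4 h tests these differences directly, and the endothelial identity and KLF-regulated lists passed in it.

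After 24 h, cells under either flow had lost most of their cell cycle expression. Mitotic genes were lower in 20 of 20 cases under both flows, with list medians of -3.55 (adjusted p = 1.9e-78) and -4.61 (adjusted p = 4.47e-99); TOP2A went from 346.5 ± 4.07 CPM in static cells to 36.09 ± 0.299 under pulsatile and 13.23 ± 0.294 CPM under oscillatory flow (SD, n = 3). DNA replication genes fell in 19 of 20 cases (medians -2.56 and -2.59) and histone genes in 14 of 14 (medians -2.22 and -2.52). RRM2, a subunit of ribonucleotide reductase, had log2 fold changes of -4.01 and -5.65. NRF2 genes rose in 20 of 20 cases under pulsatile flow (median 1.03, adjusted p = 3.45e-21) and in 18 with 1 lower under oscillatory flow (median 1.27, adjusted p = 1.39e-25), with NQO1 at 2.87 and 2.23 and the ferritin subunit FTL at 2.25 and 2.38. Vasoactive mediator genes rose in 11 of 15 with 3 lower (12 and 3 adjusted over the list alone; median 1.61, adjusted p = 9.08e-08) and in 12 with 1 lower (median 1.18, adjusted p = 7.69e-07). Except where given, counts adjusted over the list alone were the same, apart from 1 DNA replication gene that was then higher under pulsatile flow. These lists held with an estimated correlation (largest adjusted p = 0.00614).

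The KLF-regulated list rose under pulsatile flow after 24 h (14 higher and 1 lower of 16, also adjusted over the list alone; median 2.45, adjusted p = 3.08e-17, adjusted p = 0.000721 with an estimated correlation) and did not pass under oscillatory flow (10 higher, 2 lower, adjusted p = 0.0511). Glycolysis genes fell in 16 of 20 cases under both flows (1 higher under oscillatory flow), and ENO1 had log2 fold changes of -1.44 and -1.59; the lists passed (adjusted p = 8.83e-06 and 1.21e-06) but had adjusted p = 0.133 and 0.0998 with an estimated correlation. Matrix genes were 18 higher and 4 lower of 24 under pulsatile flow (median 0.969, adjusted p = 9.92e-07, but adjusted p = 0.133 with an estimated correlation). The ATF4 list was higher under oscillatory flow (13 higher, 3 lower, adjusted p = 0.00964, but adjusted p = 0.438 with an estimated correlation) and did not pass under pulsatile flow. CYP1B1 reached count ratios to static cells of 14100 (95% interval 3910 to 117000) and 1390 (383 to 11400). CYP1A1 rose by 8.59 under pulsatile flow, and from 4.1 to 1030 CPM under oscillatory flow. CMKLR1, with 1 count in all static libraries, had a ratio of 564 (101 to 22300) under pulsatile flow. That count came from replicate 2, so the size of this ratio rests on 1 library. AKR1C1, with fractional estimates, had a ratio of 61.2 (42.4 to 91.7) under oscillatory flow. INHBB (lower by a count ratio of 53.6, 95% interval 29.8 to 108), GPRIN3 (32.5, 18.4 to 63.3) and KIT (log2 fold change -4.77) fell most under pulsatile flow. FAM111B (lower by a count ratio of 69, 45.4 to 110), HIST1H2AJ (-5.90, with fractional estimates) and PBK (-5.87) fell most under oscillatory flow. Pulsatile flow called 9940 genes, 5216 higher and 4724 lower, and oscillatory flow 9792, 5045 higher and 4747 lower. Static cells were collected at 0 h only, so part of these differences can come from time in culture, and the design does not separate the 2.

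**Figure D4:**
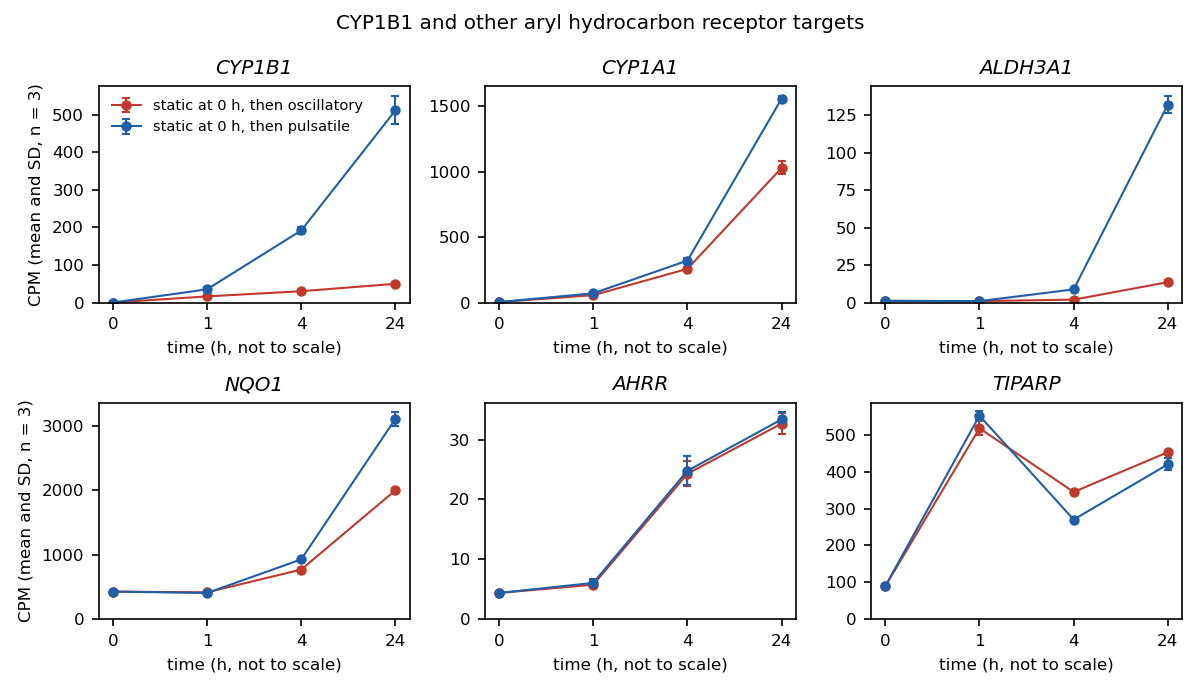
Mean and SD (n = 3) of 6 known targets of the aryl hydrocarbon receptor in CPM (vertical axes) by hours of flow (horizontal axes, not to scale), for pulsatile and oscillatory flow with static cells at 0 h. CYP1B1 stood at 512 CPM in pulsatile and 50 CPM in oscillatory flow after 24 h, and CYP1A1 at 1560 and 1030 CPM.

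The changes from static cells under both flows shared much of their direction. Static cells were taken at 0 h only. A change with time in culture would appear under both flows and cannot be told from a shared response. Genes called in the same direction against static cells numbered 788, 4319 and 8053 at 1, 4 and 24 h, against 13, 327 and 372 called in opposite directions. Those higher under both were 455, 2154 and 4114 (61.2, 794 and 1954 if calls were independent). Those lower under both were 333, 2165 and 3939 (39.5, 738 and 1665). In simulated unchanged groups that shared the static libraries, a mean of 0 genes were called in the same direction. Each simulated comparison called a mean of only 0.35 genes, so an overlap near 0 was fixed in advance. It does not show how far shared static libraries raise the overlap where many genes are called. Sharing these libraries does produce part of the correlation of log2 fold changes. The simulated groups had a correlation of 0.488 and a covariance of 0.0304. The data had correlations of 0.716, 0.633 and 0.824 and covariances of 0.095, 0.192 and 0.814. The 3 static libraries were too few to be divided between the comparisons.

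Within each flow, later times were compared with earlier ones to follow the course of expression. No static cells were collected at these times, so time under flow and time in culture cannot be told apart here. From 1 to 4 h, NRF2 genes rose in 20 of 20 cases under pulsatile flow (median 0.58, adjusted p = 2.3e-34) and in 18 under oscillatory flow (median 0.565, adjusted p = 7.63e-52). Notch and arterial genes fell back in 12 of 17 and 13 of 17 cases with 1 higher in each (medians -0.766 and -0.886, adjusted p = 2.34e-19 and 3.15e-15). KLF-regulated genes rose under pulsatile flow (11 higher, 1 lower of 16; median 1.06, adjusted p = 3.13e-18), while endothelial identity markers fell under oscillatory flow (18 of 19; median -0.427, adjusted p = 1.35e-13). Adjusted over the list alone, the counts were the same except for 13 lower Notch genes and 12 higher with 2 lower KLF-regulated genes under pulsatile flow. From 4 to 24 h, mitotic genes fell in 20 of 20 cases under both flows (medians -3.29 and -4.4, adjusted p = 1.65e-103 and 7.33e-137), and cholesterol synthesis genes fell under pulsatile flow in 22 of 23 (median -0.998, adjusted p = 1.23e-16; the same adjusted over the list alone). These calls held with an estimated correlation (largest adjusted p = 0.0496). For cholesterol synthesis genes, the pulsatile to oscillatory difference shifted by a median of -0.53 from 4 to 24 h, less than the fall under pulsatile flow. Part of that fall was therefore shared by oscillatory flow. NF-kB genes fell back from 4 to 24 h in 18 and 20 of 22 cases with 1 higher in each (the same adjusted over the list alone; medians -1.08 and -1.29, adjusted p = 0.000653 and 3.3e-05, but adjusted p = 0.149 and 0.11 with an estimated correlation).

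Under pulsatile flow 5791 genes changed from 1 to 4 h (3017 higher, 2774 lower) and 8963 from 4 to 24 h (4501 higher, 4462 lower). Under oscillatory flow 5387 changed from 1 to 4 h (2692 higher, 2695 lower) and 8757 from 4 to 24 h (4255 higher, 4502 lower). Scaled by library totals alone, the splits from 1 to 4 h were 2193 higher and 3813 lower under pulsatile and 2093 higher and 3521 lower under oscillatory flow.

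The interaction asked whether the difference between flows itself changed with time. For 4155 genes it did between 1 and 24 h (2323 shifted toward pulsatile flow, 1832 away from it), and for 2600 between 4 and 24 h (1422 and 1178). With library totals alone the split between 1 and 24 h was 1876 and 2319. KLF2 had a smaller difference at 24 than at 1 h (a change of -1.28, from 3.67 to 2.40), whereas the difference of NOS3 grew by 1.24. From 4 to 24 h the difference of NOS3 shrank (a change of -0.67, adjusted p = 0.000728). Of 20 mitotic genes, 20 shifted toward pulsatile flow from 1 to 24 h (median 0.898, adjusted p = 2.52e-15). Beside them, 12 of 14 replication-dependent histone genes shifted the same way and 0 the other (the same adjusted over the list alone; median 0.36, adjusted p = 8.02e-06, but adjusted p = 0.27 with an estimated correlation). Of 5 smooth muscle markers 1 did (also adjusted over the list alone; list adjusted p = 0.0163, but adjusted p = 0.0726 with an estimated correlation). In turn 16 of 18 ATF4 genes shifted away from pulsatile flow (median -1.23, adjusted p = 8.75e-23), as did 20 of 23 cholesterol synthesis genes (21 adjusted over the list alone; median -0.595, adjusted p = 1.56e-15). The mitotic, ATF4 and cholesterol synthesis lists held with an estimated correlation (adjusted p = 0.029, 0.00167 and 0.0474). As many or more genes were called in 11 of 100 splits of these libraries for either interaction, the real one included. The 10 others moved time points unevenly between the flows by at least 2 libraries, which turns the change with time into an interaction. The count over all splits therefore mixes in the effect of time and cannot decide on chance. Of the 44 even splits, 0 gave as many. They mix times within each group, which widens the spread there, so they cannot decide on chance either.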

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

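The tests of mitotic genes without the most abundant genes and of aryl hydrocarbon receptor targets were chosen only after the result was seen, and so was the removal of the trend on exon length and GC content.

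Some genes stood out because the difference between pulsatile and oscillatory flow itself changed between times, by the interaction test. Of 46 panel and top genes looked at, 34 had a changed difference at 24 h against 1 h, 17 shifting toward pulsatile flow and 17 away from it, and 6 more changed at 24 h against 4 h alone. The top genes were taken for a large difference at 1 of these times, which favours a changed difference. Among all tested genes, 4155 of 13469 (30.8%) had one between 1 and 24 h. Values are log2 changes of the pulsatile to oscillatory difference.

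From 1 to 24 h, NOS3 shifted by 1.24 (but by -0.67 from 4 to 24 h, adjusted p = 0.000728), THBD by 1.21 and PECAM1 by 0.41. EDN1 shifted by -0.94 and PTGS2 by -0.49. KLF2 shifted by -1.28 and HEY1 by -1.01, so their differences were smaller at 24 h. S1PR2 shifted by -2.02, from higher in pulsatile flow at 1 h to no called difference at 24 h. The adhesion molecule VCAM1 shifted by 0.84. Early responders ANGPTL4 (-1.17) and ARC (-1.03) shifted away from pulsatile flow, and so did EGR1 (-2.82, with 17 counts in pulsatile flow at 24 h), CTGF (-1.14) and CYR61 (-0.75). NQO1 shifted by 0.68 and MKI67 by 1.14.

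Among genes with the largest differences, C10orf10 (0.76), SPRY1 (1.44) and PDK4 (1.22), which were lower in pulsatile flow at 1 h, shifted toward it by 24 h. NOV (5.41, with 22 counts in oscillatory flow at 24 h), APOL4 (3.63), AQP1 (5.01), MN1 (1.77) and STC1 (5.28) shifted toward pulsatile flow. So did PI16 (10.41), LCN6 (9.06) and CMKLR1 (5.97), whose fitted values rest on few counts in oscillatory flow and are no bound. CXCR4 (-1.43), FILIP1 (-2.71), GALNTL2 (-1.73), ANGPT2 (-3.31), CPA3 (-2.94), NUPR1 (-2.80) and ESM1 (-1.81) shifted away. From 4 to 24 h alone, CCL2 shifted by 1.79, F3 by 0.50, PDE4B by 0.39 and DDIT4 by 0.24, and KLF4 shifted by -1.42 and ANKRD1 by -0.37. Against their shifts from 1 to 24 h, APOL4 (-1.77, adjusted p = 0.00271, with 15 counts in oscillatory flow at 4 h) and MN1 (-1.40, adjusted p = 0.00298) shifted away from pulsatile flow from 4 to 24 h.

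Lists whose shift also passed with an estimated correlation were, from 1 to 24 h, the KLF-regulated genes (median 1.28, adjusted p = 0.00113 with an estimated correlation), cholesterol synthesis genes (-0.595), mitotic genes (0.898), ATF4 genes (-1.23), angiogenic tip cell genes (-0.513, adjusted p = 0.0317) and endothelial identity markers (0.226, adjusted p = 0.0382). From 4 to 24 h they were cholesterol synthesis genes (-0.53, adjusted p = 0.0114), mitotic genes (0.921, adjusted p = 0.00341) and ATF4 genes (-0.703, adjusted p = 0.00253). Beside the mitotic genes, histone genes shifted toward pulsatile flow from 1 to 24 h (median 0.36, adjusted p = 8.02e-06) and from 4 to 24 h (median 0.219, adjusted p = 3.09e-05), but had adjusted p = 0.27 and 0.332 with an estimated correlation. Smooth muscle markers passed in both (adjusted p = 0.0163 and 0.00464, but adjusted p = 0.0726 and 0.0506 with an estimated correlation).

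The first pattern weighed was the set of 659 genes called between the flows at 1 h, where longer genes leaned higher in pulsatile flow (rho 0.32). With each library's trend on exon length and GC content taken out, 90% of the calls stayed in the same direction (593 of 659, 95% interval 87.4 to 92.2), which argues against that trend as the whole source of the calls. With every library thinned to 14196623 counts, 81.8% stayed called (539 of 659, 95% interval 78.6 to 84.7), and for the others a loss of power and an effect of depth cannot be told apart. The kind of flow stays open as a biological explanation, untested by any further experiment here.

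The second pattern was the higher level of mitotic genes in pulsatile flow at 24 h (list median 0.855 over 20 genes). Taking out the trend on length and GC content left a median of 0.828 (0.806 to 0.899 without any 1 of the 6 libraries). That trend was weak at 24 h (rho -0.119 with exon length and -0.0307 with GC content). Its removal could move the median only a little and decides little on such a bias. Scaling to totals without the 10 most abundant genes left 0.794 (0.762 to 0.863). The 10 most abundant genes of a library held a mean of 13.3% of counts in oscillatory and 12.4% in pulsatile flow at 24 h. These shares are too close for their removal to move the median much, so this scaling was no test of its own. The kind of flow stays open as a biological explanation, untested here.

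The third pattern was CYP1B1, higher in pulsatile flow at 24 h by 3.35 (SE 0.08) on the log2 scale. Its difference was 3.37 with the trend on length and GC content taken out. That trend, fitted over all genes, was weak at 24 h (rho -0.119 with exon length and -0.0307 with GC content). Its removal could hardly move a difference of this size, so it was no test of its own. A stronger aryl hydrocarbon receptor signal in pulsatile flow is a candidate explanation, but the other 5 targets looked at had a median of 0.593 (SE 0.121 for the middle one) and went both ways, so that it cannot be told apart from a change of CYP1B1 by another route. The kind of flow stays open here too.

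Other splits of the same libraries were counted for each comparison. For the 13 comparisons of 3 against 3 libraries, 1 of 10 splits gave as many genes as the real one, which is itself. With 10 splits, a share under 0.05 cannot be reached. The other splits mix libraries of both groups, so a real difference widens their spread. Low counts in them do not show what chance alone gives. Between the flows, the highest other split called 0, 0 and 7 genes at 1, 4 and 24 h, against 659, 3603 and 5295. For pulsatile flow against static cells it called 26, 0 and 0, against 2632, 6607 and 9940, and for oscillatory flow 2, 0 and 0, against 1019, 6248 and 9792. For the time comparisons it called 0 in each case, against 5791, 8963, 5387 and 8757. For the interactions, 11 of 100 splits gave as many genes or more, so chance is not excluded by this count: the highest other splits called 7608 (real 4155) and 7161 (real 2600). A split that calls so many points to a structure of the samples. The 10 other splits as large were those that moved time points unevenly between the flows by at least 2 libraries. Such a move turns the large change with time into an interaction. While 0 of the 44 even splits gave as many, they mix times within each group, which widens the spread there.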

How the results depend on the processing

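Removal of the trend on exon length and GC content, of RPPH1 and RMRP, and of the main axis of variation within groups were chosen after seeing the data. The following counts of called genes moved by more than 1.5 times. At an adjusted p of 0.01, 394 genes were called between the flows at 1 h, and the shared response of both flows to static at 1 h held 397 genes (788 at 0.05), since the threshold is stricter. Against a 1.5-fold change, glmTreat called 59, 490 and 836 genes between the flows at 1, 4 and 24 h, since it asks for a larger change; it was not run for the other comparisons. With the axis of variation within groups as a term, oscillatory flow against static cells at 1 h gave 1554 genes. This axis held 21% of the variance within groups, and its loadings went with exon length (rho 0.354, across genes) and GC content (0.424).

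Without 1 library, the 1 h counts ran from 423 to 567 between the flows, from 1477 to 2895 for pulsatile flow and from 538 to 1032 for oscillatory flow against static cells, so these 3 rest on single libraries most. The lowest came without replicate 1 of oscillatory flow, replicate 3 of pulsatile flow and replicate 2 of oscillatory flow. Low counts also came without replicate 3 of pulsatile flow between the flows (430), without static replicate 2 for pulsatile flow (1739), and without static replicates 2 and 3 for oscillatory flow (620 and 657). At 4 and 24 h the counts between the flows ran from 2952 to 3223 and from 4596 to 5071. Across the other settings, 547 to 932, 3172 to 4176 and 4691 to 5798 genes were called between the flows at 1, 4 and 24 h, with the DESeq2 Wald test lowest each time; the causes were not tested. With the replicate number as a block the counts were 639, 3541 and 5235. The numbers do not pair the samples: correlations between deviations of libraries with the same number lay between -0.119 and 0.0851. Scaling by library totals alone or by RLE factors shifted the share of higher calls by more than 10 points in 6 comparisons; for pulsatile flow at 4 h against static cells it went from 52.1% to 40%.

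Of 510 list results, 215 passed at the preset correlation, 80 with an estimated correlation and 359 with fry, which asks another question. With the replicate block 219 passed, and 205 with the trend taken out, where lists were tested on log2 CPM instead of counts. Of 582 results for named genes, 533 were called; 501 of these stayed called in the same direction under every alternative at the same threshold, 32 lost the call or reversed at least once, and 22 that were not called passed at least once. Over 10475 alternatives, 10276 kept direction and side of the threshold, 129 lost the call, 69 gained it and 1 reversed. The reversal was RPS6 in pulsatile flow against static cells at 1 h, which went from -0.14 to 0.007853 when the trend on length and GC content was taken out; the cause was not tested beyond that. KLF4 in oscillatory flow against static cells at 1 h lost its call without replicate 3 of static cells (1.31) and without replicate 2 of oscillatory flow (1.29).

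Depth limits genes with few counts. In data simulated on the 24 h libraries with 200 changed genes, a change of 1.2-fold was recovered for 36% of 50 genes, and 7.05% of all calls were false. The real comparison of the flows at 24 h called 5295 genes, so its cutoff was less strict and the simulated recovery does not carry over to it. The simulation did not vary depth. Small changes can go undetected, so a gene that did not pass is not shown to be unchanged.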

Other observations

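No test in this part was planned except those of the fixed lists; the receptor and its targets were looked at only after the result was seen.

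Other gene groups moved between the flows at 1 h by small amounts. Heat shock genes were higher in 3 of 15 cases and lower in 0 (5 and 0 adjusted over the list alone; adjusted p = 0.00803, but adjusted p = 0.538 with an estimated correlation), with the cochaperone CHORDC1 higher (0.34). Cholesterol synthesis genes were higher in 2 of 23 and lower in 0 (4 and 0 adjusted over the list alone; adjusted p = 0.0199, but adjusted p = 0.538 with an estimated correlation), the opposite direction to 24 h, and INSIG1, the sterol sensor that retains SREBP in the endoplasmic reticulum, rose by 0.69. DNA replication genes had 1 lower of 20 (1 adjusted over the list alone; adjusted p = 0.019, but adjusted p = 0.525 with an estimated correlation), which was the cyclin CCNE2 (-0.39). Lists of endothelial-mesenchymal transition, endoplasmic reticulum chaperone, glycolysis, vasoactive, coagulation, cilium, p53, fibroblast, leukocyte, lymphatic and nuclear retained RNA genes did not pass between the flows at any time in the main test. With the length and GC trend taken out, the chaperone genes passed as higher at 4 h (adjusted p = 0.0182). Some of these lists passed with fry, such as the chaperone and glycolysis genes at 4 h (adjusted p = 0.00843 and 0.000963).

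Against static cells, further groups changed with time. After 1 h, clock genes rose in 5 of 15 cases under pulsatile flow (median 0.127, adjusted p = 6.58e-07) and in 4 under oscillatory flow (5 adjusted over the list alone; median 0.0943, adjusted p = 0.000136), with 0 lower, and both held with an estimated correlation (adjusted p = 0.000529 and 0.00401). SNAI1, a transcription factor of mesenchymal transition, rose by 3.26 and 2.01. Cholesterol synthesis genes rose after 4 h in 17 and 16 of 23 cases with 2 lower in each (18 and 16 adjusted over the list alone; adjusted p = 1.88e-07 and 7.43e-07, but adjusted p = 0.165 and 0.196 with an estimated correlation), and after 24 h of pulsatile flow 20 were lower and 1 higher (adjusted p = 0.00029, but adjusted p = 0.387 with an estimated correlation). Interferon-stimulated genes fell in 13 of 20 cases with 1 higher after 4 h of oscillatory flow (adjusted p = 0.00232, but adjusted p = 0.211 with an estimated correlation). TMEM100, a BMP target of arterial endothelium, had a count ratio of 66 (95% interval 33.2 to 154) after 24 h of pulsatile flow. Of its 8 static counts, 5 came from replicate 1, so this ratio rests largely on 1 library.

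Some markers of other cell types were present, given here in CPM of library totals. RGS5, a pericyte marker that endothelium can also express, had 114 CPM in static cells, 46.4 after 24 h of oscillatory and 174 after 24 h of pulsatile flow. KRT18 went from 268 CPM in static cells to 51.8 and 62.3, LYVE1, a lymphatic marker, from 11.7 to 2.19 and 2.55, and the fibroblast collagen COL1A2 from 2.38 to 8.91 and 15.7. Other fibroblast markers went both ways: PDGFRA (0.622 to 5.95 and 4.98) and COL3A1 (2.35 to 3.14 and 6.26) rose, while DDR2 (63.5 to 43 and 41.9) and THY1 (0.379 to 0.0193 and 0.0189) fell. The epithelial markers EPCAM, CDH1, KRT5 and KRT14 had 10, 0, 0 and 0 counts in all libraries, and the leukocyte marker PTPRC had 12. Erythroid markers were too low to be tested, and the list of mitochondrially encoded genes had 0 members in the table.

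One hypothesis was put to a test: that flow acts on the aryl hydrocarbon receptor, and more so when pulsatile. CYP1A1 stood at 4.1 CPM in static cells, 1030 after 24 h of oscillatory and 1560 after 24 h of pulsatile flow, and AHRR, the feedback repressor of the receptor, at 4.37, 32.7 and 33.4 CPM. Between the flows at 24 h, ALDH3A1 differed by 3.28, NQO1 by 0.64, CYP1A1 by 0.59, AHRR by 0.03 and TIPARP by -0.11, against 3.35 for CYP1B1. AHR, the receptor gene itself, was lower in pulsatile flow at 1, 4 and 24 h (-0.20, -0.64 and -0.28; adjusted p = 0.00275, 9.95e-16 and 7.23e-07), and TIPARP was lower at 4 h (-0.36), which goes the other way. The median of the 5 targets, 0.593, lies far below the difference of CYP1B1, but the members split, so the hypothesis that the receptor is more active in pulsatile flow may or may not hold. NQO1 is also an NRF2 target, and time in culture goes with flow in the comparisons with static cells.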
